A study of Homo sapiens with 9 samples.

How the data were processed

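The files hold read counts per gene for 9 RNA-seq libraries of Daoy cells, 1 table per library. Per the labels' protocols, poly(A) RNA was made into TruSeq v2 libraries, a kit that does not mark the strand, and read as 100 nt single ends. The labels of single samples name one HiSeq instrument, and the design text names a further model without assigning libraries to it. The counts were deposited as raw whole numbers for 57820 versioned Ensembl gene identifiers, and the submitters' processing notes name bcl2fastq, HISAT2, HTSeq, DESeq2 and the builds GRCh37 and hg19. Versions, settings and the roles of these tools are not given in the sources used here. Because the kit is unstranded, reads of a gene and of its antisense or overlapping partner cannot be told apart in these counts.

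Each table ends with 5 HTSeq summary lines that name no gene. They held 20.3% to 35.8% of all reads and stayed out of library sizes and tests. Reads assigned to genes numbered 8216568 to 13030572 per library, and 22958 to 25143 genes had at least 1 count. A gene with no count in a library could still be at up to 0.230 to 0.365 CPM (reads scaled to library size) there (3 counts of the library's total), and such limits cover counting error only. Symbols were matched by identifier to GENCODE v29, which covered 39880 identifiers (68.97%). That annotation is on another build, so it served only for symbols, transcript GC content and length, and no coordinates are given. The mitochondrially encoded genes had 0 counts in all libraries, so that list could not be tested.

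Groups came from the labels: control (2), shDDX3X (3), wild type re-expression (1) and mutant re-expression (3, 1 library for each mutant). The labels do not say whether replicates are independent cultures, so p-values of single genes measure only the spread between these samples, which may be technical. The number series (A, 3 libraries; B, 6) was inferred from numbers in the deposited names, and no label ties it to a sequencing run. Across all genes it separated the libraries on the first principal component (44.0% of the variance), and 1818 of 16155 genes differed between series in the fit. Within-group pairs of libraries were checked for copies of one library. They differed by far more than sampling noise (chi-square per degree of freedom 11.2 to 96.3).

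The main test was edgeR's robust quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization on genes with at least 1 CPM in at least 2 libraries (16155 genes). Group and series were terms and all 9 libraries shared 1 estimate of the spread, with 4 residual degrees of freedom and a prior of 5.85. Adjusted p-values follow Benjamini and Hochberg and a gene was called at 0.05. With 1 wild type library, its comparisons assume that it varies as the other groups do. All re-expression libraries are in series B, so their pooled folds against knockdown also depend on the controls through the series term. The limits of the DDX3X folds are 95% confidence intervals. The test was checked on simulated counts for the same 16155 genes with 200 changed genes, all with a mean of at least 5 CPM. Recovery among genes below that level was not measured. For knockdown against control it recovered 46% of genes changed 2-fold and 99% of those changed 4-fold, for wild type against knockdown 12% and 89%, and for mutants against knockdown 37% and 98%. It called 0 genes when none was changed, in counts simulated without a difference between series. These simulations held no GC trend of single libraries and gave every gene the spread typical of its expression level. Their rates may therefore be too favourable and may not hold in the real data.

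For pathways, cell type markers and complexes, 28 gene lists (895 genes, 866 matched) were fixed before the data were examined, as were the comparisons, the main test, most alternatives and the rule for naming genes. Of these, 27 lists could be tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison. This sets the members of a list against the other genes. Its p-values rest on that assumed correlation and can be small with few libraries. The same test with an estimated correlation called 0 lists in every comparison, and so did fry. Within series, a list's median log2 ratio was set against 10000 random lists matched on expression, and pooled medians against random lists matched on expression, transcript GC content and length. For the reversal of knockdown changes, the 200 most lowered and 200 most raised genes were taken from the series A libraries (mean of at least 5 CPM, 11617 genes eligible) and read in series B.

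Genes were named by rule. For knockdown against control these are the 10 most raised and 10 most lowered called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap. For each list up to 4 members in the direction of a called list, or 2 of a list not called, are given, and where fewer than 3 genes were called the 3 with the smallest p. IGFBP3, COLEC12 and TNS4 in the mutants were the 3 genes called there, and genes repeated between comparisons, like those named between the hairpins, were chosen after their values were seen. The Y-linked paralogue of DDX3X, which the rule also names, is not reported singly and enters only a summed count.

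Alternatives were RLE normalization, DESeq2 1.42.0, no filter or a mean of at least 5 CPM, no series term, each series alone, only the groups compared, the 3' UTR hairpin only, each replicate left out and the replicate number as a block. Within series B, control, knockdown and wild type have 1 library each, so the spread of a fit there comes from the mutants (2 residual degrees of freedom). Within series A, 1 control faces knockdowns by different hairpins (1 residual degree of freedom). Calls from these fits are therefore no test of replication between series. After the data were seen, a GC correction was added. A loess curve (span 0.5) of each gene's deviation on GC content was fitted per library over genes with a mean of at least 5 CPM and used as an offset. On simulated counts with a GC trend it took the Spearman correlation of fold change with GC from 0.577 to 0.001.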

Results

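RNA from Daoy cells, an established human line derived from a medulloblastoma (a tumour of the cerebellum), was sequenced in 9 libraries to ask how expression depends on DDX3X, an X-linked DEAD-box RNA helicase, and on mutant forms of it. The 2 control libraries were from parental cells (control 1) and vector cells (control 2). The 3 knockdown libraries carried a doxycycline-inducible short hairpin RNA against the 3' untranslated region of DDX3X (shDDX3X 1 and 3) or against its open reading frame (ORF; shDDX3X 2), induced by 72 h in doxycycline at 1 µg/ml. The labels give 1 treatment text for every library and do not say of each control whether it received the drug, so an effect of doxycycline is not separated from knockdown in comparisons with control. The remaining 4 libraries re-expressed FLAG-tagged DDX3X in cells with the 3' UTR hairpin, as the wild type (1 library) or as the G302V, R534H or P568L mutant (1 library each, taken as 3 replicates of a mutant class). Reads assigned to genes numbered 12619786 and 9960144 in the controls, 12519035, 12200748 and 8639551 in the knockdowns, 8318129 with wild type and 8216568, 9576711 and 13030572 with G302V, R534H and P568L. The libraries formed 2 series by the numbers in their deposited names. Control 1, shDDX3X 1 and shDDX3X 2 (series A) had 5.24% to 5.73% unaligned reads, and the other 6 libraries (series B) had 19.6% to 24.0%. Series was a term of the fits, and values within series are given beside pooled ones.

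DDX3X itself (ENSG00000215301.5) was lower in all 3 knockdown libraries. Its normalised level was 567.9 ± 163.1 CPM (reads scaled to library size, SD, n = 2) in the controls and 190 ± 55.4 CPM (SD, n = 3) in the knockdowns, a log2 fold change of -1.60 ± 0.24 (SE; fold 0.329, 95% interval 0.228 to 0.474, edgeR adjusted p = 0.0357). Within series, DDX3X in the knockdowns was 36.4% and 20.3% of the parental level with the 3' UTR and ORF hairpins of series A, and 40.3% of the vector level in series B. In the re-expression lines DDX3X was at 43.1% of the vector level with wild type and at 43.7%, 46.7% and 53.4% with G302V, R534H and P568L. Counts per gene do not tell RNA of the construct from endogenous DDX3X RNA, so these levels cannot be assigned to either. The mutant class averaged 217 ± 22.5 CPM (SD, n = 3) and the wild type library had 195 CPM. Against the knockdowns, the fold was 1.18 for wild type (95% interval 0.7 to 1.99, adjusted p = 1) and 1.31 for the mutants (0.87 to 1.98, adjusted p = 0.842). The adjusted p for DDX3X, shDDX3X vs control, was 0.369 without control 1, and 0.0902, 0.117 and 0.133 without the G302V, R534H and P568L libraries, with the log2 fold change at -1.31 without control 1.

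**Figure D1:**
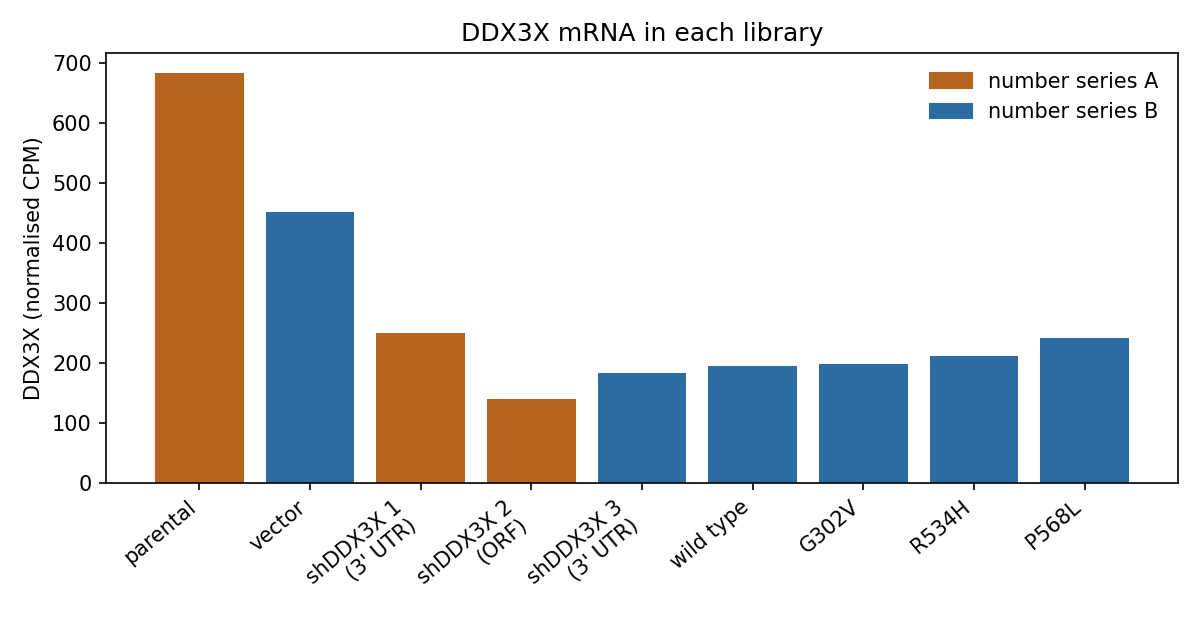
Normalised DDX3X level (CPM, linear axis from 0) in each of the 9 libraries, 1 bar per library, coloured by number series. Both controls (683 and 453 CPM) lie above all knockdown and re-expression libraries, which lie between 139 and 249 CPM.

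Knockdown of DDX3X lowered SULF1, TP63 and GAS7 several-fold and raised ADAM12, TPM1 and COL7A1. SULF1, which removes sulfate groups from heparan sulfate, fell from 61.7 ± 6.46 CPM (SD, n = 2) to 6.53 ± 2.67 CPM (SD, n = 3), a log2 fold change of -3.31 ± 0.29 (SE, adjusted p = 0.00848). TP63, a p53-family transcription factor, fell from 21.1 ± 3.42 to 2.74 ± 0.49 CPM (log2 -2.91 ± 0.30, adjusted p = 0.0108), and GAS7 from 119 ± 21.6 to 12.97 ± 4.69 CPM (log2 -3.36 ± 0.45, adjusted p = 0.024). Also among the 10 most lowered genes were TNS4, a focal adhesion tensin (log2 -3.55), BMPER, a regulator of bone morphogenetic proteins (-3.41), ITIH5 (-3.23), CMKLR1, the chemerin receptor (-2.78), PPARGC1A, a coactivator of mitochondrial biogenesis (-2.55), COLEC12, a scavenger receptor (-2.54), and IL17RD, an inhibitor of fibroblast growth factor signalling (-2.32), with adjusted p from 0.0108 to 0.0488. In the other direction, ADAM12, a metalloprotease, rose from 66.6 ± 1.05 to 228 ± 47.0 CPM (log2 1.80 ± 0.17, adjusted p = 0.00852). TPM1, an actin-binding tropomyosin, rose from 528 ± 53.9 to 1729 ± 117 CPM (log2 1.72 ± 0.20, adjusted p = 0.016). COL7A1, the collagen of anchoring fibrils, rose from 181 ± 98.1 to 705 ± 83.4 CPM (log2 2.17 ± 0.27, adjusted p = 0.0175). The other most raised genes were IGFN1 (3.38), MIR663AHG (3.34), FJX1 (2.29), the protease ADAMTS9 (2.21), HIC2 (1.92), the lipid kinase subunit PIK3CD (1.92) and CSRNP1 (1.71), with adjusted p from 0.024 to 0.0488.

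In all, 109 of 16155 genes were called between knockdown and control, 46 raised and 63 lowered, and 103 of them differed by at least 2-fold. The balance depended on the tool and threshold: DESeq2 called 1324 genes, 997 raised and 327 lowered (98 of the 109 among them), and at an unadjusted p under 0.05 edgeR had 2098 higher and 1461 lower. Fits within 1 series had 1 control, and in series B also 1 knockdown library. Their calls do not test replication and are not counted here. The median log2 ratio of the raised genes was 1.49 in series A and 1.14 in series B, and that of the lowered genes -2.14 and -1.89, but the genes were selected on these same libraries, so the medians are not independent evidence of direction. The genes raised were richer in GC (median 56.8%) than the genes tested (48.2%), and those lowered poorer (44.6%). In the parental library the level relative to the other libraries fell with a gene's GC content (Spearman -0.71 across 11590 genes, which are not independent replicates), while in the vector library it rose (0.383). With the GC trend of each library removed, a step chosen after seeing the data, 287 genes were called and 95 of the 109 were among them, COL7A1 at a log2 fold change of 1.35. Fits without control 2 or without shDDX3X 3 compare shDDX3X 1 and 2 with the parental library alone, the library with the strongest GC trend. A fit without control 1 compares shDDX3X 3 with vector alone. The number of calls depended on the setting and on single libraries. It was 0 with only the groups compared, 6 with no series term and 17 with a mean CPM of at least 5. It was 4 without control 1, 14 without shDDX3X 1, and 9, 6 and 1 without G302V, R534H and P568L, and 2064, 313 and 2087 without control 2, shDDX3X 2 and shDDX3X 3.

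The list of interferon-stimulated genes had a lower median after knockdown in both series. By the naming rule, the members named here are those that changed in the list's direction. Of 46 list members, 34 were lower and 12 higher, with a median log2 fold change of -0.56 (camera adjusted p = 3.37e-08, adjusted p = 0.909 with an estimated correlation). BST2, the antiviral membrane protein tetherin, fell (log2 -1.61 ± 0.28 SE, adjusted p = 0.0449) and was the only member called over all genes; adjusted over the list alone, 15 were lower and 2 higher. The transcription factor IRF9 had a log2 fold change of -1.90 (adjusted p = 0.0511) and the oligoadenylate synthetase OAS1 -1.93 (0.0598). The list median was -0.31 in shDDX3X 1, -0.92 in shDDX3X 2 and -0.72 in shDDX3X 3, each below the central 95% of 10000 random lists matched on expression. Leaving out any 1 control, knockdown or mutant library kept the list's call at the preset correlation, and with the GC trend removed the median was -0.59.

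Inflammatory NF-kB targets were higher, and more so in series A. Of 31 members, 30 were higher (median log2 1.06, camera adjusted p = 2.16e-08, adjusted p = 0.909 with an estimated correlation); none was called over all genes, against 8 raised adjusted over the list alone. CSF1, a macrophage growth factor, had a log2 fold change of 0.95 (adjusted p = 0.0511), NFKB2 1.36 (0.0775), IER3 1.21 (0.0862) and the cytokine IL11 3.40 (0.0889). The list median was 1.52 and 1.5 in shDDX3X 1 and 2 but 0.31 in shDDX3X 3, and with the GC trend removed the pooled median was 0.93. The median difference between the knockdown effects of series B and A was -1.27 (camera adjusted p = 2.4e-06, adjusted p = 0.951 with an estimated correlation), and the call against control was lost in series B alone (adjusted p = 0.085) and without control 1 (0.0909).

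**Figure D2:**
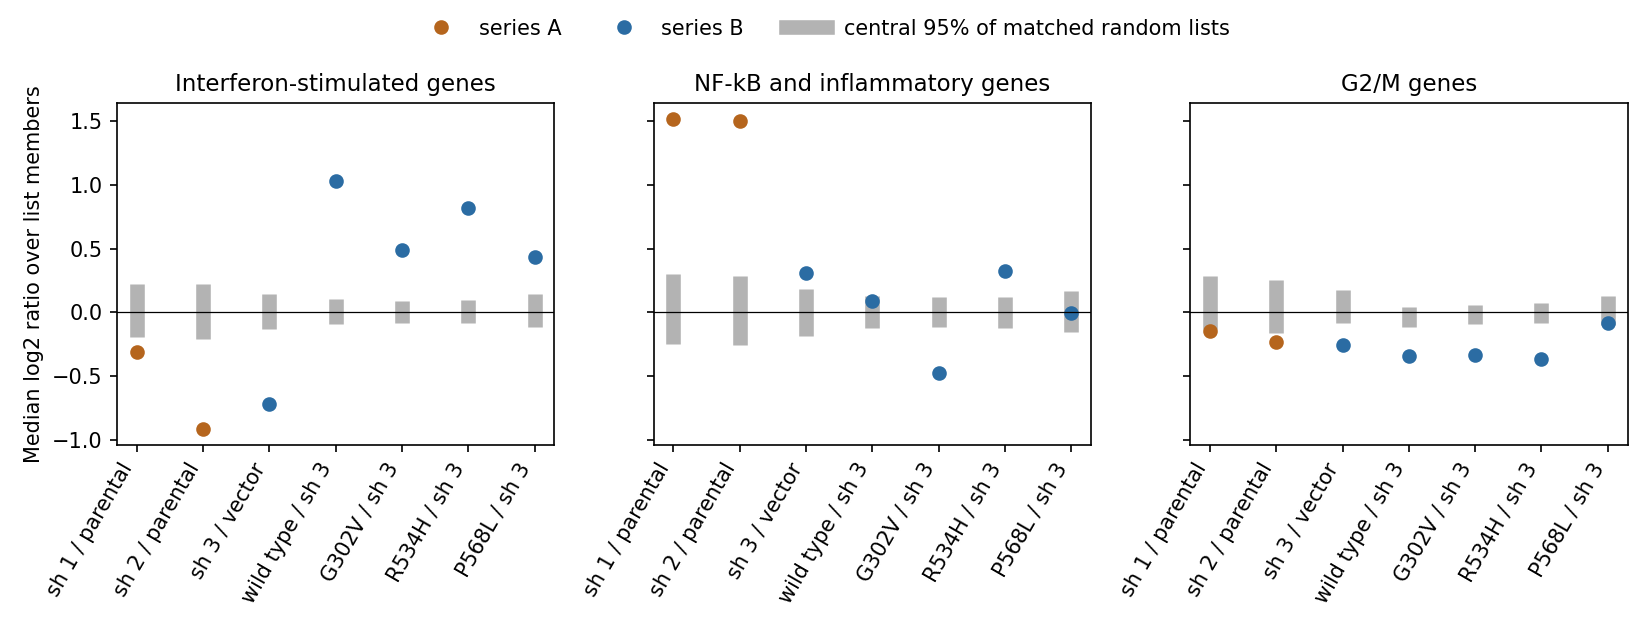
Median log2 ratio of 3 gene lists in each library against the reference of its own series (knockdowns against their control, re-expression libraries against shDDX3X 3), with bars for the central 95% of 10000 expression-matched random lists. The interferon list lies below that range in all 3 knockdowns (-0.31, -0.92 and -0.72) and above it in all 4 re-expression libraries. The -0.72 and all 4 re-expression ratios use shDDX3X 3, so part of each opposite sign comes from that library's own deviation.

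Lists of matrix, growth and cell cycle genes had smaller medians. The mesenchymal list had 25 of 40 members higher (median log2 0.40, camera adjusted p = 0.022, adjusted p = 0.909 with an estimated correlation), with COL5A1 raised from 608 ± 237 to 1566 ± 295 CPM (log2 1.51, adjusted p = 0.0175) and COL1A1 raised by 1.49 on the log2 scale (adjusted p = 0.0449; 0.93 and 0.0509 with the GC trend removed). Adjusted over the list alone, 9 mesenchymal members were higher and 2 lower. TGF-beta targets had 15 of 20 higher (median 0.51, adjusted p = 0.0198, adjusted p = 0.909 with an estimated correlation), with PMEPA1 raised (0.89, adjusted p = 0.0482) and 4 higher adjusted over the list alone. YAP targets had 19 of 26 higher (median 0.36, adjusted p = 0.0198, adjusted p = 0.909 with an estimated correlation), with FJX1 raised and IGFBP3, which binds insulin-like growth factors, lowered (-1.84, adjusted p = 0.016); adjusted over the list alone, 5 were higher and 1 lower. S phase genes had 27 of 35 lower (median -0.22, adjusted p = 0.0163; 0 adjusted over the list alone) and G2/M genes 27 of 36 (median -0.17, adjusted p = 0.0198; 3 lower adjusted over the list alone), with TYMS at -0.96, TTK at -0.75 and TOP2A at -0.65 (adjusted p = 0.0684, 0.0681 and 0.0684). Both cell cycle lists had an adjusted p = 0.909 with an estimated correlation. With the GC trend removed, the TGF-beta and G2/M lists were not called (adjusted p = 0.468 and 0.101). In series B alone, the mesenchymal, TGF-beta and YAP lists were not called (0.252, 0.0969 and 0.798). Without a series term, neither were the TGF-beta (0.0577) and G2/M (0.144) lists, and with a mean CPM of at least 5 neither were the mesenchymal (0.0793), TGF-beta and YAP (both 0.0529) lists.

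Single libraries also carried the calls of these lists, shDDX3X vs control. A fit without control 1 reduces to shDDX3X 3 against vector, as in series B alone. Fits without control 2 and without shDDX3X 3 both reduce to shDDX3X 1 and 2 against the parental library. Without control 1 the adjusted p was 0.275 for the mesenchymal, 0.0909 for the TGF-beta and 0.791 for the YAP list. Without control 2 it was 0.167 for G2/M and 0.0925 for the S phase, mesenchymal and TGF-beta lists. Without shDDX3X 1 it was 0.0581 for YAP targets. Without shDDX3X 2 it was 0.0762, 0.0806 and 0.0578 for the G2/M, S phase and mesenchymal lists, and without shDDX3X 3 it was 0.184 for G2/M and 0.0888 for the S phase, mesenchymal and TGF-beta lists.

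The other 20 lists were not called between knockdown and control (camera adjusted p from 0.136 to 0.995). Members of some still passed alone: GAS1, a hedgehog co-receptor, fell (log2 -2.24, adjusted p = 0.0251), as did EGR3, an immediate early transcription factor (-2.68, adjusted p = 0.0482), and ESRP1, an epithelial splicing regulator (-2.51, adjusted p = 0.0449). The list medians were -0.30 for epithelial markers, 0.08 for sonic hedgehog targets, -0.09 for Wnt targets, -0.03 for neural stem and glial genes, 0.05 for neuronal genes and 0.59 for the 6 haematopoietic markers measured. Lists close to the helicase's work on RNA had medians of -0.02 (DEAD-box helicases), 0.04 (translation initiation), 0.04 (stress granule proteins) and 0.04 (ribosomal proteins). Stress and metabolism lists had medians of -0.19 (ATF4 targets), 0.10 (unfolded protein response), -0.04 (p53 targets), 0.01 (immediate early genes), 0.09 (hypoxia and glycolysis), 0.11 (autophagy and lysosome), -0.08 (cholesterol synthesis) and -0.03 (oxidative phosphorylation). Matrix proteases had a median of 0.02. The 10 replication histones measured, of 44 listed and 20 matched by symbol, had 0.21. With the GC trend removed, epithelial markers were called (median -0.61, camera adjusted p = 0.0176, adjusted p = 0.826 with an estimated correlation).

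The ORF and 3' UTR hairpins were compared to see whether the site targeted mattered. No gene was called by edgeR (0 of 16155; 1472 at an unadjusted p under 0.05, and 87 by DESeq2). The smallest adjusted p was 0.0838, shared by 7 genes. Their log2 fold changes, ORF against 3' UTR hairpin, were 1.64 for KCTD10, 2.05 for the cyclin CCND3, 5.34 for SPANXA2, 1.46 for FAM120A, 1.89 for EEF1A1P6, -1.62 for the tropomyosin TPM3 and -1.70 for MOB3A. The values of SPANXA2, from a family of near-identical genes, and of EEF1A1P6, a pseudogene, are uncertain because reads can be shared with their copies. Without shDDX3X 1, the ORF hairpin lies only in series A and the 3' UTR hairpin only in series B. The parental and vector controls alone then separate the series, so genes called in that fit mix their difference with the hairpin site. With 1 ORF library the comparison rests on the spread of the other groups, and 27 genes were called once the GC trend was removed. The count was 89 without control 1, 92 without control 2, 925 without shDDX3X 1 and 85 without shDDX3X 3.

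Re-expression of wild type DDX3X was compared with knockdown to ask which changes it undid. Several genes had higher values with wild type, but none was called: SULF1 was at 32.9 CPM (log2 2.53 ± 0.41 SE against the knockdowns), TSPAN11 at a log2 fold change of 2.91, CLDN16 at 2.78, IFITM1 at 2.96, BST2 at 1.82 and IFI44L at 1.75, all with adjusted p = 1. ADAM12 (-1.19), DAPK1 (-1.16) and ATOH8 (-1.19) had lower values. Because shDDX3X 3 is the only knockdown library of series B, a fit without it separates the series by the parental and vector controls alone. Counts from that fit mix the difference between those controls with re-expression. No gene passed by edgeR (0; 472 at an unadjusted p under 0.05, and 3 by DESeq2), and 596 were called when shDDX3X 3 was left out, 1 without control 1 and 1 without control 2.

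As a group, interferon-stimulated genes were higher with wild type DDX3X in 39 of 46 members (median log2 0.91, camera adjusted p = 5.31e-32; 12 higher adjusted over the list alone, 0 over all genes). The adjusted p was 0.207 with an estimated correlation. Within series B the median was 1.03 against shDDX3X 3 and 0.26 against vector. G2/M genes were lower in 34 of 36 (median -0.44, adjusted p = 3.02e-11, adjusted p = 0.692 with an estimated correlation; 0 adjusted over the list alone), with GTSE1 at -0.78, KIF20A at -0.74, CCNB1 at -0.72 and PLK1 at -0.62. The other lists called had smaller medians: ATF4 targets -0.20 (adjusted p = 0.000898; CHAC1 -1.41, STC2 -1.39), YAP targets -0.37 (0.00149), ribosomal proteins -0.12 (0.00699), cholesterol synthesis 0.17 (0.0341; INSIG1 0.86), NF-kB targets -0.31 (0.0341) and neural stem and glial genes 0.33 (0.0415). With an estimated correlation the adjusted p was 0.693 for neural stem and glial genes and 0.842 for the other 5. The ribosomal median lay inside the central 95% of random lists matched on expression, GC content and length (-0.129 to 0.001). NF-kB targets did not hold in series B, where the median against shDDX3X 3 was 0.09 (adjusted p = 0.896). YAP targets and ribosomal proteins were at adjusted p = 0.0542 there. Without a series term the ATF4 list turned to higher with wild type (camera adjusted p = 0.011), and the ribosomal (0.616), cholesterol (0.468), NF-kB (0.157) and YAP (0.0805) lists were not called. Neural stem and glial genes were not called with a mean CPM of at least 5 (0.472), nor NF-kB targets with the GC trend removed (0.0694). Only the interferon and G2/M lists kept their call whichever single control, knockdown or mutant library was left out. For wtDDX3X vs shDDX3X, the call was lost without control 1 (cholesterol 0.0578, ribosomal and YAP 0.0579, NF-kB 0.981), control 2 (0.0521, 0.0595, 0.98), shDDX3X 1 (NF-kB 0.0659), shDDX3X 2 (NF-kB 0.122, neural stem 0.0618), shDDX3X 3 (ATF4 0.0749, cholesterol 0.346, neural stem 0.727) or R534H (neural stem 0.161). The direction of the NF-kB list turned to higher without control 1 and without control 2. Without either control, the knockdown libraries alone separate the series. Wild type is then set against shDDX3X 3 only, as in series B alone, so these losses are the same contrast and not separate evidence.

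The 3 mutants were compared with knockdown in the same way. SULF1 again had a higher value (log2 2.14, edgeR adjusted p = 0.505), as had LUM, a matrix proteoglycan (1.99, adjusted p = 0.505), A2M, a protease inhibitor (3.29, adjusted p = 0.505) and BST2 (1.56, adjusted p = 0.72). CRISPLD2 (-1.93, adjusted p = 0.306), EMILIN2 (-2.37, adjusted p = 0.637) and SCUBE3 (-1.85, adjusted p = 0.637) had lower values. None was called (0 of 16155; 894 at an unadjusted p under 0.05, and 26 by DESeq2), and 996 genes were called without shDDX3X 3, 1 without control 1 and 1 without control 2. The fit without shDDX3X 3 separates the series by the parental and vector controls alone, so the 996 genes mix their difference with re-expression. The fold changes of mutants against knockdown fell with GC content across genes (Spearman -0.571, and -0.375 for wild type against knockdown). Against shDDX3X 3 in its own series, SULF1 was higher by log2 2.89 with wild type and by 2.5, 2.65 and 2.37 with G302V, R534H and P568L, where the knockdown itself had moved it by -3.90. GAS7, moved by -3.72, was higher by 2.36 with wild type and by 2.53, 2.21 and 0.66 with the mutants. TPM1, moved by 1.54, had ratios of -0.98 with wild type and of -1.10, -0.63 and -0.52 with the mutants. These ratios share the shDDX3X 3 library, so part of each opposite sign comes from that library's own deviation.

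Interferon-stimulated genes were higher with the mutants in 39 of 46 members (median log2 0.56, camera adjusted p = 8.91e-15, adjusted p = 0.727 with an estimated correlation; 2 higher adjusted over the list alone, 0 over all genes), and G2/M genes lower in 34 of 36 (median -0.27, adjusted p = 1.19e-07, adjusted p = 0.727 with an estimated correlation; 1 adjusted over the list alone). Within series B the interferon median against shDDX3X 3 was 0.49 with G302V, 0.82 with R534H and 0.43 with P568L. The G2/M median was -0.34, -0.37 and -0.09. These medians all use shDDX3X 3, so part of each comes from that library's own deviation. The remaining calls were NF-kB targets (-0.34, adjusted p = 0.0103), YAP targets (-0.26, adjusted p = 0.032), ribosomal proteins (-0.11, adjusted p = 0.0358), TGF-beta targets (-0.27, adjusted p = 0.0358) and epithelial markers (-0.22, adjusted p = 0.0358), with 1 TGF-beta target and 1 epithelial marker lower adjusted over the list alone. With an estimated correlation the adjusted p was 0.807 for the NF-kB, YAP and ribosomal lists and 0.727 for the other 2. The TGF-beta and epithelial medians lay inside the central 95% of random lists matched on expression, GC content and length (-0.304 to -0.023 and -0.464 to 0.172). In series B alone the NF-kB (0.939), YAP (0.46), ribosomal (0.19) and epithelial (0.19) lists were not called. With the GC trend removed the TGF-beta and epithelial lists were not called (0.454 and 0.0543), and 4 further lists were: S phase genes (-0.17, adjusted p = 0.00996), immediate early genes (0.21, 0.00996), autophagy and lysosome (0.21, 0.0144) and matrix proteases (0.20, 0.0177). These 4 had an adjusted p = 0.738, 0.516, 0.738 and 0.516 with an estimated correlation. Without a series term the NF-kB (0.0688), epithelial (0.116) and YAP (0.448) lists were not called, and the ribosomal and TGF-beta lists turned to higher (both 0.961).

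The interferon call of the mutants against knockdown held without any 1 control, knockdown or mutant library. Fits without control 1 and without control 2 both reduce to the mutants against shDDX3X 3, as in series B alone, so their losses are the same contrast. The G2/M list had an adjusted p = 0.101 without shDDX3X 3. NF-kB targets were lost without control 1 (0.936), control 2 (0.972) or G302V (0.566), and YAP targets without control 1 (0.523), control 2 (0.51), shDDX3X 1 (0.0775) or G302V (0.339). Ribosomal proteins were lost without control 1 (0.2), control 2 (0.192), shDDX3X 2 (0.0753), shDDX3X 3 (0.0725), R534H (0.105) or P568L (0.278). TGF-beta targets were lost without shDDX3X 1 (0.0628), shDDX3X 3 (0.174), G302V (0.148) or P568L (0.0808). Epithelial markers were lost without control 1 (0.157), control 2 (0.135), shDDX3X 1 (0.061), shDDX3X 2 (0.0513), shDDX3X 3 (0.101) or P568L (0.0948).

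Mutant and wild type re-expression were compared to ask where the mutants departed from wild type. No gene was called by edgeR (0; 315 at an unadjusted p under 0.05, and 0 by DESeq2). The genes with the smallest p included the non-coding RNA MEG3 (log2 1.48 higher with the mutants) and PRUNE2 (1.13), and among those lower MGAT3 (-3.19), COLEC12 (-2.04) and the keratin KRT8 (-1.33), all with adjusted p = 1. Interferon-stimulated genes were lower with the mutants in 42 of 46 (median -0.30, camera adjusted p = 5.69e-06, adjusted p = 0.546 with an estimated correlation), with IFITM1 at -1.46 and OAS3 at -0.42. The median against wild type was -0.55 with G302V, -0.22 with R534H and -0.23 with P568L. Neural stem and glial genes were lower in 15 of 18 (median -0.57, adjusted p = 0.00031; MSI1 -0.88, HES1 -0.59), Wnt targets in 17 of 23 (-0.38; 0.00313; NKD2 -1.79) and epithelial markers in 5 of 9 (-0.13; 0.00148; 2 lower adjusted over the list alone, 0 in the other 5 lists), each at an adjusted p = 0.406 with an estimated correlation. The epithelial median lay inside the central 95% of random lists matched on expression, GC content and length (-0.4 to 0.211). Matrix proteases were higher in 16 of 26 (0.21; 0.00772; ADAMTS5 0.81, ADAM12 0.64) and ATF4 targets in 28 of 34 (0.17; 0.0415; VLDLR 0.61). These 2 had an adjusted p = 0.406 and 0.842 with an estimated correlation.

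The wild type group is 1 library, and other single libraries gave as many lists. P568L differed from the other libraries of series B in its GC trend (Spearman -0.111, against 0.383 to 0.576). A list count of its own therefore cannot be assigned to the mutation. The fold changes of mutants against wild type also fell with GC content across genes (Spearman -0.268). Set against the other 3 re-expression libraries, wild type gave 6 lists, G302V 6, R534H 7 and P568L 9. For mutDDX3X vs wtDDX3X, the matrix protease list was not called without R534H (adjusted p = 0.0697). The ATF4 list was not called without control 1 (0.0572), control 2 (0.0619), shDDX3X 3 (0.0597) or P568L (0.566), nor without a series term (0.223). With a mean CPM of at least 5, the ATF4 (0.0601) and Wnt (0.132) lists were not called. Mutants were also set against each other 1 library at a time. No gene was called by edgeR between G302V and R534H (0; 223 at an unadjusted p under 0.05), G302V and P568L (0; 231) or R534H and P568L (0; 128). Against wild type the counts were 0 for each mutant, with 136, 185 and 335 at an unadjusted p under 0.05, and against knockdown 0 for each by edgeR with 3, 12 and 2 by DESeq2 for G302V, R534H and P568L.

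The re-expression lines were last compared with the controls, to see what remained changed. Single genes are given here, and gene lists against the controls under the other observations. A fit without control 2 separates the series by the knockdown libraries alone. It then has the parental library as its only control, so its counts rest on that library. With the mutants 3 genes fell: TNS4 (log2 -4.19, edgeR adjusted p = 0.0121), IGFBP3 (-2.38, adjusted p = 0.0121) and COLEC12 (-3.08, adjusted p = 0.0328). All 3 had also fallen with knockdown (-3.55, -1.84 and -2.54). With wild type their fold changes against the controls were -2.60, -1.32 and -1.04 (adjusted p = 0.991). COLEC12 in series B was at log2 1.16 against shDDX3X 3 with wild type and at -0.75, -0.62 and -0.97 with the mutants. The difference between mutants and wild type was -1.59, -1.06 and -2.04 for the 3 genes and passed for none (adjusted p = 1). DESeq2 called 163 genes between mutants and control and 5 between wild type and control, where edgeR called 0 (712 at an unadjusted p under 0.05). The mutant count was 0 without any 1 of the mutants and 58, 774, 54 and 69 without control 1, control 2, shDDX3X 2 and shDDX3X 3, and the wild type count was 607 without control 2.

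To ask how far re-expression returned knockdown genes towards the controls without reusing a control, gene sets were taken from series A and read in series B. The 200 genes most lowered in series A (median log2 -1.63) were higher in the vector library than in shDDX3X 3 by a median of 0.67 (164 of 200). They were higher by 0.46 with wild type (155 of 200), 0.30 with G302V (139), 0.37 with R534H (132) and 0.14 with P568L (114; central 95% of matched random sets -0.04 to 0.08). With the GC trend removed the P568L median was 0.01, inside its random range. The 200 genes most raised in series A (median 3.03) had a median of -0.11 in vector. The series A medians come from genes selected as most extreme in that series, so they are inflated. Their size against series B does not measure a difference between the series. With the GC trend removed, the series A median of the raised set was 2.06. The small change of this set in series B left little for re-expression to reverse. The median was 0.02 with wild type, and -0.14, -0.08 and -0.23 with G302V, R534H and P568L. Of these values only that of wild type lay inside its random range, from sets matched on expression but not on GC content. After removal of the GC trend the raised set had a median of -0.19 in vector, -0.045 with wild type, now below its random range (-0.033 to 0.071), and -0.21 with G302V. R534H (-0.01) and P568L (0.035) then lay inside theirs. All of these values are against the same library, shDDX3X 3.

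**Figure D3:**
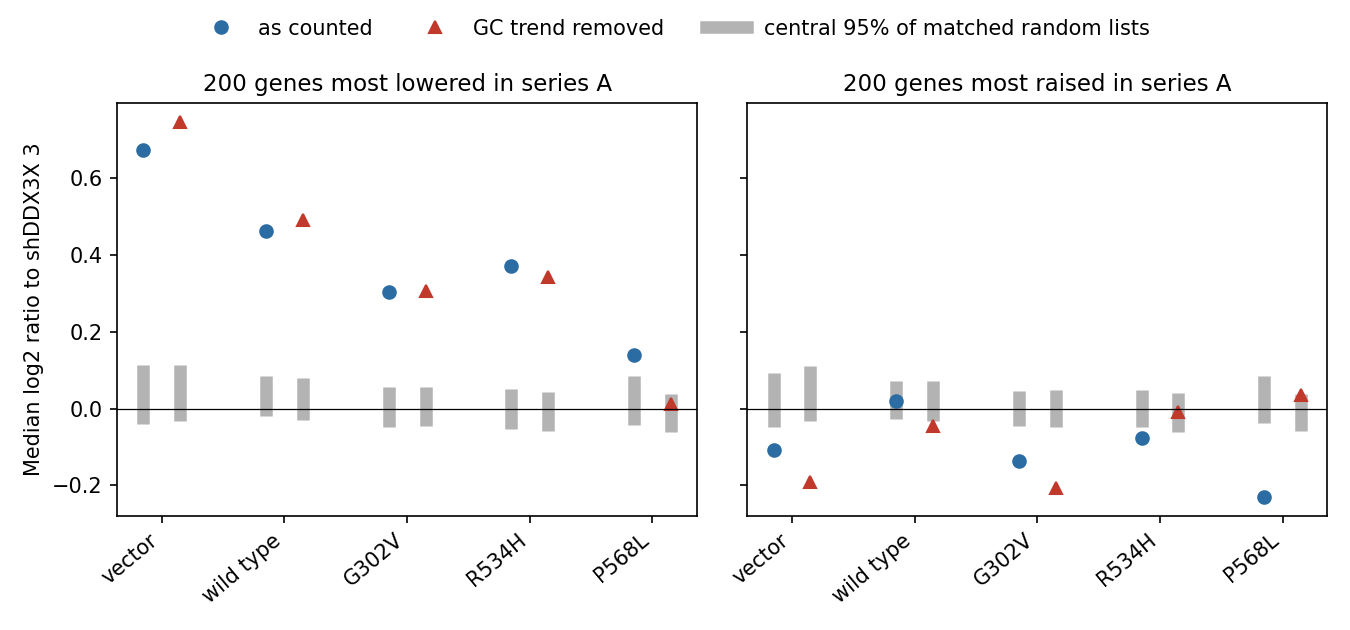
Median log2 ratio against shDDX3X 3 of the 200 genes most lowered and the 200 most raised by knockdown in series A, in the vector library and the 4 re-expression libraries of series B, as counted and with the GC trend removed. As counted, the lowered genes are higher in vector (0.67), wild type (0.46), G302V (0.30), R534H (0.37) and P568L (0.14), while the raised genes lie between -0.23 and 0.02.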

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

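The tests of the series as a source of the interferon pattern and of GC content as a source of the series difference were chosen after the results were seen, and so was every value with the GC trend removed.

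DDX3X counts in the 4 re-expression libraries stood at 43.1% to 53.4% of the vector level, close to the 40.3% of shDDX3X 3, although a construct was added. Reads of the construct counted under the paralogue or pseudogenes of DDX3X are argued against: together these had at most 0.35 CPM in a re-expression library, where over 100 would be needed. Reads lost as ambiguous stay open, since the ambiguous share was 0.011 percentage points higher than in the other series B libraries, with an SD of 0.061 among the re-expression libraries. Low expression of the construct, or a protein level not mirrored in RNA, may equally lie behind it and was not tested.

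The interferon-stimulated list was lower with knockdown (median log2 -0.56) and higher with wild type (0.91) and mutant (0.56) re-expression than with knockdown. A difference between the series is argued against as the whole cause, since the median was -0.719 for shDDX3X 3 against vector within series B. GC content and gene length are argued against too: random lists matched on both and on expression reached at most 0.12 at the upper end of their central 95% for mutants against knockdown. For the fall with knockdown, deviation of shDDX3X 3 alone is argued against by the -0.31 of shDDX3X 1 against the parental library, below its matched random lists. For the rise with re-expression it stays open, since every ratio to knockdown within series B uses shDDX3X 3. The list calls kept without that library rest on the parental and vector controls to separate the series. An effect of the knockdown and re-expression that the design names stays open and untested, as do differences between separately made lines, since no call held with an estimated correlation and DDX3X counts did not separate re-expression from knockdown (fold 1.18 and 1.31).

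The knockdown effect differed between series A and series B for 516 genes (39 with a higher and 477 with a lower log2 fold change in series B; edgeR, 2197 at an unadjusted p under 0.05), 4 of them among the 109 knockdown genes. Among them were H1-10 (-4.73), LAMA5 (-4.46), ISG15 (-3.73), H2AX (-3.69) and MT2A (-3.40). ISG15 is an interferon-stimulated gene, and its knockdown effect was not alike in the series, although the interferon list had a lower median in both. The 516 genes had a median GC content of 63.4% against 48.2% of those tested. With each library's GC trend removed, 44 were called, 42 of them among the 516, so GC content may account for most of this difference, with the parental library showing the strongest trend (Spearman -0.71). What the remaining 44 reflect stays open, since each series has 1 control and the controls differ in kind, parental against vector.

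Beside these, 3 lists differed in knockdown effect between series B and A, as tested by camera on the interaction: NF-kB targets by a median of -1.273 (adjusted p = 2.4e-06; -0.916 with the GC trend removed), immediate early genes by -0.668 (0.0106; not called with the GC trend removed, adjusted p = 0.0507) and YAP targets by -0.643 (0.0102; -0.403). With an estimated correlation all 3 had an adjusted p = 0.951. With the GC trend removed, autophagy and lysosome genes (0.445, adjusted p = 0.00955) and ribosomal proteins (-0.167, 0.0382) were called as well, at an adjusted p = 0.677 and 0.79 with an estimated correlation.

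Mutant minus wild type re-expression differed for 6 lists, with medians of -0.573 for neural stem and glial genes, -0.377 for Wnt targets, -0.302 for interferon-stimulated genes, -0.132 for epithelial markers, 0.206 for matrix proteases and 0.165 for ATF4 targets. With an estimated correlation no list was called (adjusted p = 0.546 for interferon-stimulated genes, 0.842 for ATF4 targets and 0.406 for the other 4). A mutant library set against the other 3 re-expression libraries gave up to 9 lists, so the difference of wild type from the mutants is no greater in number of lists than that of a single library from the rest. The 6 lists therefore cannot be assigned to the mutations.

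For mutants against knockdown, edgeR called 0 genes with the real grouping and at most 0 with the other splits (10 of 10 splits gave as many). At an unadjusted p under 0.05 the real split had 894 genes and the highest other split 618. With 10 splits a share under 0.05 cannot be reached.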

How the results depend on the processing

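The GC correction, with and without the parental library, and the list tests in series B alone and without single libraries were chosen after the data were seen. Over all alternatives, 238 values kept their side of the threshold (counts of genes or lists: within 1.5 times), 93 counts moved by over 1.5 times, 13 values lost their call and 2 medians of the reversal test changed sign with 1 of the 2 values outside its random range. Of the values of named genes, 2223 were the same, 236 lost a call, 152 gained one, 12 moved and 0 changed sign. The cause was not tested except where given.

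The counts of called genes (knockdown against control 109, wild type and mutants against knockdown 0, mutants against control 3) rested on the setting. With no filter on low counts (33139 genes, prior degrees of freedom infinite against 5.85), they were 1920 for knockdown, 57 and 166 for wild type and mutants against knockdown, 36 for mutants against wild type, 658 and 52 for mutants and wild type against control, 292 for the ORF against the 3' UTR hairpin, 2 for G302V and 1 for R534H. With a mean CPM of at least 5, knockdown gave 17 genes and mutants against control 1, DDX3X was at -1.608 (adjusted p = 0.0556, in a range over all its alternatives of 1.73e-15 to 0.491), and the called lists numbered 4 for knockdown and 6 for mutants against control. With no series term, knockdown gave 6 genes and DDX3X -1.579 (adjusted p = 0.145). DESeq2 gave 1324 (knockdown; 997 raised, 327 lowered), 3 (wild type against knockdown), 26 (mutants against knockdown), 163 and 5 (mutants and wild type against control), 87 (ORF against 3' UTR), 3 (G302V), 12 (R534H) and 2 (P568L).

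The GC correction gave 287 genes (96 raised, 191 lowered, against 46 and 63), 33 for mutants against control and 27 for the hairpins. Without the parental library as well, these were 4 for knockdown (DDX3X -1.248, adjusted p = 0.345), 1 each for wild type and mutants against knockdown and 43 for mutants against control. Series B alone gave 5 and 12 genes for wild type and mutants against knockdown, 10 and 435 against control, and 6 lists for mutants against control. For knockdown, series B alone gave 142 genes (36 of the 109 among them), series A alone 1244 (76 of the 109), and the 3' UTR hairpin alone 313. With only the groups compared, counts were 0 for knockdown (DDX3X -1.6, adjusted p = 0.305), 1 and 1 for wild type and mutants against knockdown and 401 for mutants against control; the residual degrees of freedom fell from 4 to 2 for knockdown.

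With the replicate block, knockdown gave 0 genes and DDX3X was at -1.58 (adjusted p = 0.491). The groups share only 2 numbers, and the deviations of same-numbered libraries correlated at 0.388 for number 1 and -0.285 for number 2. With 2 controls, their deviations mirror each other, so this cannot test pairing by number. The signs followed the series, with positive values between a control and the knockdowns of its own series (0.388, 0.285 and 0.486). With an estimated correlation, or with fry, 0 lists were called in each of the 6 comparisons. Among called lists, the direction turned without a series term for ATF4 targets with wild type against knockdown (to higher, camera adjusted p = 0.011), with mutants against control (0.172) and with wild type against control (0.543), and for ribosomal proteins and TGF-beta targets with mutants against knockdown (both 0.961). It also turned for NF-kB targets with wild type against knockdown without control 1 (0.981) and control 2 (0.98). Also without a series term, the interferon (0.146) and autophagy (0.0617) calls of wild type against control were lost. In the reversal test, the raised set changed sign with the GC correction for wild type (-0.045, below its random range) and P568L (0.035, inside it). The wild type median, 0.02 and inside its random range, changed sign to -0.006, also inside its range, with sets from shDDX3X 1 alone, and was 0 with the RLE scaling. With the GC correction the set's R534H value lay inside the random range at -0.01, as it did with 100 genes (-0.064) and with a mean CPM of at least 1 (-0.045). The lowered set for P568L was 0.011 with the GC correction.

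Without single replicates, the ranges were 1 to 2087 genes for knockdown (DDX3X -1.821 to -1.312), 0 to 596 for wild type against knockdown (DDX3X 0.098 to 0.603), 0 to 996 for mutants against knockdown (DDX3X 0.25 to 0.756), 0 to 0 for mutants against wild type, 0 to 774 and 0 to 607 for mutants and wild type against control, 85 to 925 for the hairpins and 0 to 0 for each mutant alone. Called lists numbered 3 to 7, 4 to 8, 3 to 7, 5 to 11, 5 to 10 and 4 to 9 in the same order of comparisons. The largest gene counts came from fits that reduce to the parental library as the only control or separate the series by the controls alone. They are therefore not the effect of leaving out a single deviating library. Depth of 8216568 to 13030572 counts limited genes near 1 CPM. The single wild type library limits its comparisons, where 12% of simulated 2-fold changes were recovered among genes with a mean of at least 5 CPM.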

Other observations

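No test was run for this part beyond those of the comparisons; the choice of lists and genes described was made after their values were seen.

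Mitotic genes were lower in every re-expression library than in the vector control. Against the controls, G2/M genes were lower in 36 of 36 members with wild type (median log2 -0.55, camera adjusted p = 3.5e-22, adjusted p = 0.468 with an estimated correlation) and in 35 of 36 with the mutants (-0.46; 9.94e-15; 0.348). Within series B the median against vector was -0.26 in shDDX3X 3, -0.57 with wild type, and -0.59, -0.59 and -0.30 with G302V, R534H and P568L. S phase genes against the controls were at -0.27 with wild type (adjusted p = 1.01e-06; 0.559 with an estimated correlation) and -0.32 with the mutants (3.75e-06; 0.625). Both lists kept their call at the preset correlation when any 1 control, knockdown or mutant library was left out. Within series B the S phase median against vector was -0.21 in shDDX3X 3, -0.31 with wild type, and -0.37, -0.41 and -0.19 with G302V, R534H and P568L. That of the interferon list was -0.72 in shDDX3X 3, 0.26 with wild type, and -0.25, 0.09 and -0.04 with the mutants. Pooled, NF-kB targets stayed above the controls, with a median of 0.70 with the mutants (camera adjusted p = 7.23e-06) and 0.77 with wild type. The mutant call was lost with an estimated correlation, in series B alone and without control 1 or shDDX3X 3. Relative to the mean of all libraries, the list was at -1.006 in parental and -0.266 in vector. It was at 0.123 with wild type and -0.495, 0.549 and 0.074 with G302V, R534H and P568L. ATF4 targets were at -0.33 with wild type and -0.26 with the mutants.

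Against the controls the mutants also had higher matrix protease genes (median 0.43, camera adjusted p = 0.00158; 7 higher and 1 lower adjusted over the list alone) and lower epithelial markers (-0.51; 2.53e-05; 3 lower adjusted over the list alone), each with an adjusted p = 0.348 with an estimated correlation. The matrix protease median against vector was 0.04 in shDDX3X 3, 0.14 with wild type and 0.19, 0.56 and 0.37 with G302V, R534H and P568L. Epithelial markers also had a lower median with wild type against the controls (-0.41, 1 library), where the list was not called. A lower median was thus not seen with the mutants alone. Relative to the mean of all libraries their median was 0.498 in vector and -0.063 in shDDX3X 3. It was -0.073 with wild type and -0.089, -0.29 and -0.417 with G302V, R534H and P568L. Without control 2 the adjusted p was 0.16 for matrix proteases and 0.434 for epithelial markers. Sonic hedgehog targets, of interest in a medulloblastoma line, were at -0.25 (0.0246; 0.625 with an estimated correlation), with GAS1 at -1.31 and MYCN at -2.36 (adjusted p = 0.239 and 0.303 by edgeR). That call was lost in series B alone (0.111), without a series term (0.504), with a mean CPM of at least 5 (0.21) and without control 1 (0.105), control 2 (0.169), shDDX3X 3 (0.0581) or P568L (0.144).

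CRISPLD2 did not follow the knockdown. Its log2 fold change was -0.09 for knockdown against control (edgeR adjusted p = 0.853), and -0.97 with wild type and -1.93 with the mutants against knockdown (adjusted p = 1 and 0.306).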
